A study of Homo sapiens with 6 samples.

How the data were processed

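The study measured RNA in the human cell line PANC1 in 6 libraries, 3 labelled NC and 3 labelled siRNA. Per the labels' protocols, RNA was extracted with TRIzol, and libraries were made with a dUTP method that keeps the strand and sequenced as paired 150 bp reads on an Illumina instrument. The protocols describe poly(A) selection for eukaryotes beside rRNA depletion for prokaryotes, and do not say whether strand was used in counting. The genome build was hg38 per the submitters' processing notes; the aligner, quantifier and annotation are not given in the sources used here.

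The deposited table lists 20307 protein-coding genes, 75 of them with a repeated symbol, with 2 columns per library. The authors gave the first kind of column as FPKM, per the file headers. The authors gave the second kind as counts, per the file headers, but its values are a scaled read signal. Within a library, 91.1% to 91.7% of the low values above 0 lie within 0.1 of a whole multiple of a step. High values were left out of this check. The step differs between libraries, and the column totals are nearly equal at 12.0 to 12.3 M (1000000). The step was taken as the size of 1 read, which gave the depth of each library. The columns hold no raw counts, and reads were only estimated from the step. Count models were therefore not used, and the test planned for normalised values was applied to the FPKM. No counting interval or floor is given for single genes. 1 line of the table is not analysed here. The value columns were mapped to samples by their names, with 0 left unmapped.

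The loci written in the table hold the GRCh38 gene of the same identifier, with a slack of 1000 bases, for 7.90% of the genes, so positions were taken from GENCODE 29 on GRCh38 by gene identifier, which matched 19498 genes. 7897 genes share a locus with another gene of the table.

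Genes with at least 1 FPKM in 3 or more of the 6 libraries were kept (11569), and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (limma-trend, empirical Bayes with trend and robust options, group as the only term, all 6 libraries). P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 was a call. Fold changes are siRNA minus NC on the log2 scale with the pseudocount of 1. For EIF3B and RAB14 an exact two-sided permutation test on the log2 values was added. For each of 39 gene lists, written before the data were examined, the calls were counted over all genes tested and adjusted over the list alone. The 35 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. KEGG pathways written in the deposited table, 238 with at least 10 tested genes, were tested in the same way.

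The genes named were fixed before the data were examined: EIF3B and RAB14; the 10 largest rises and 10 largest falls among calls with groups that do not overlap and a mean of at least 5 FPKM; up to 4 called members of each list by adjusted p; up to 3 members by level of the eIF3, G1/S, DNA replication and RAB lists; and the 3 most abundant markers of other cell types. Counts of the epithelial junction and keratin list are not given here, and CLDN1 and ESRP1 are the members described. The rule on markers was applied within the haematopoietic and endothelial list and within the fibroblast and stellate cell list, which brought in CD14, ITGAM, THY1 and RGS5. LHX1, which is more abundant than these, is not described. Other genes named were chosen after their values were seen, namely COL1A2, DCN, KRT13 and the genes of the closing section.

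The model was tested on simulated data with the real means and spreads. Of 50 changed genes per size among 11569, it recovered 18% at a log2 change of 0.5, 54% at 1, 82% at 1.5 and 98% at 2, with 6 false calls in all. The alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, quantile normalisation, median centring, the replicate number as a block, each library left out, a 2-fold minimum, and, added after the data were seen, the scaled counts, scaled counts of at least 10, and removal of trends in GC content and transcript length (GENCODE 29) from each library.

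A scan of words of 7 bases in 3' UTRs related log2 change to each word over 10970 genes with a 3' UTR of at least 50 bases and 15473 words present in at least 100 genes, with UTR length, GC content and expression level as further terms, in Python 3.11.15. It was tested on simulated data in which a word was given a known fall: a fall of 0.1 was found first in 4 of 5 runs and falls of 0.2 and 0.3 in 5 of 5. Gene labels were permuted 100 times.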

Results

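Messenger RNA was sequenced from PANC1, an established human pancreatic carcinoma cell line. The 6 libraries fell into 2 groups of 3, labelled NC and siRNA. The labels did not name the gene that the siRNA was directed against, and the title of the series named EIF3B, a scaffold subunit of the translation initiation factor eIF3, together with RAB14, a small GTPase of endosomal membrane traffic. Depth was estimated from the size of 1 read in the deposited scaled columns, in units of 1000000 reads, at 9.19, 13.5 and 10.5 in NC 1 to 3 and at 12.9, 15.8 and 11.1 in siRNA 1 to 3. Between 11373 and 11438 genes reached 1 FPKM (fragments per kilobase of transcript and 1000000 fragments) in each NC library, and 11519 to 11610 did so in each siRNA library. Transcripts of the mitochondrial genome made up 3.10% ± 0.26 of the summed FPKM in NC and 2.63% ± 0.35 in siRNA (SD, n = 3 per group). The first principal component of the tested genes held 34.7% of the variance and separated the groups. The second (21%) set NC 1 apart from the other NC libraries, and the third (17.8%) set siRNA 3 apart from the other siRNA libraries.

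The comparison of siRNA with NC asked which transcripts differed in PANC1 cells treated with an siRNA in a study of EIF3B, and whether RAB14 was among them. EIF3B stood at 178, 150 and 161 FPKM in NC 1 to 3 and at 34.6, 36.9 and 34.9 FPKM in siRNA 1 to 3. Its mean went from 163 ± 14.3 FPKM to 35.5 ± 1.27 FPKM (SD, n = 3 per group), which left 21.8% of the NC level, and all 3 siRNA libraries carried the loss. RAB14 fell as well, from 42.6 ± 1.84 FPKM to 23.9 ± 2.92 FPKM (SD, n = 3 per group), or 56.1% of the NC level. Its single values were 42.8, 40.7 and 44.4 FPKM in NC 1 to 3 and 26.5, 24.6 and 20.7 FPKM in siRNA 1 to 3. IL8, CXCL1, CCL20 and EREG were among the transcripts that rose, and HMGCS1 and ELOVL5 among those that fell.

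On the log2 scale EIF3B (ENSG00000106263, GRCh38 chromosome 7, 2354086 to 2380745) fell by 2.16 ± 0.09 (SE; limma-trend, adjusted p = 5.29e-06). RAB14 (ENSG00000119396, GRCh38 chromosome 9, 121178137 to 121223014) fell by 0.81 ± 0.12 (SE; limma-trend, adjusted p = 0.0109). The RAB14 call missed the threshold without NC 3 (adjusted p = 0.0549), without siRNA 2 (adjusted p = 0.0535) and without a filter on low values (adjusted p = 0.0583), with the direction kept in each. Over all alternatives its adjusted p ran from 5.15e-06 to 0.0583. An exact two-sided permutation test on the 6 values gave p = 0.1 for either gene, which is the smallest p that 3 libraries against 3 allow.

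**Figure D1:**
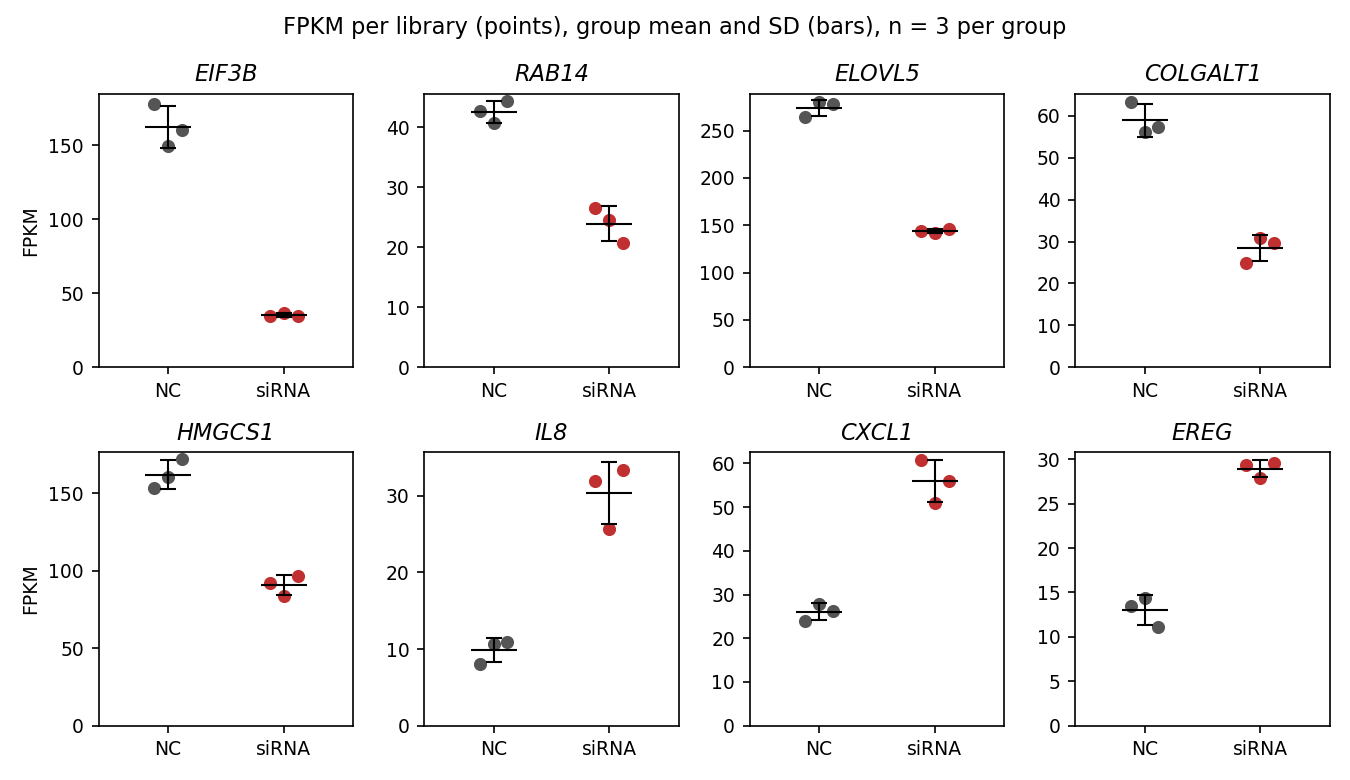
FPKM of 8 genes in each of the 6 libraries (points), with the mean and SD of each group of 3 (bars), on axes that start at 0. EIF3B went from a mean of 163 FPKM in NC to 35.5 FPKM in siRNA and RAB14 from 42.6 to 23.9 FPKM, and no siRNA library overlapped an NC library for any of the 8 genes.

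Of the 11569 genes tested, 235 changed at an adjusted p under 0.05, 144 of them higher and 91 lower in siRNA (61.3% higher). A change of at least 2-fold was met by 28 of the higher and 10 of the lower genes. Among these 10 were the low-level keratinocyte genes S100A9 (−2.49), KRT13 (−2.08) and S100A8 (−2.07), whose source is left open in the closing section. The largest rises among genes with a mean of at least 5 FPKM were those of IL8 (log2 change 1.53, from 9.89 to 30.3 FPKM), G0S2 (1.28), DMKN (1.20), SLC41A2 (1.20), CCL20 (1.19), PARP3 (1.19), LYRM1 (1.13), ITGA2 (1.12, from 9.98 to 23.0 FPKM), PPCDC (1.10) and EREG (1.10, from 13.0 to 28.9 FPKM). IL8 and CCL20 encode chemokines, ITGA2 a collagen-binding integrin subunit and EREG a ligand of the epidermal growth factor receptor. After EIF3B, the largest falls among genes with such a mean were those of CPD (−1.04), COLGALT1 (−1.03, from 59.0 to 28.5 FPKM), XRCC3 (−1.01), CDCA7 (−0.99), ELOVL5 (−0.92, from 274 to 144 FPKM), VDAC1 (−0.87, from 253 to 138 FPKM), C1orf63 (−0.87), RPA1 (−0.86, from 49.1 to 26.4 FPKM) and PNN (−0.86). COLGALT1 glycosylates collagen, ELOVL5 elongates unsaturated fatty acids, VDAC1 is a channel of the outer mitochondrial membrane and RPA1 binds single-stranded DNA during replication and repair. SLC41A2 and PPCDC lost their calls with any one library left out and on scaled counts (log2 changes 0.58 and 0.70, adjusted p = 0.0505 and 0.0611). CPD kept its call only without NC 1 and XRCC3 only without siRNA 3, and neither had one on scaled counts (−0.86 and −0.52, adjusted p = 0.121 and 0.0618). G0S2 kept its call only without siRNA 1 and C1orf63 only without siRNA 3, PNN lost it without NC 2, NC 3, siRNA 1 or siRNA 2, RPA1 without NC 2, NC 3 or siRNA 2, and CCL20, LYRM1 and CDCA7 without siRNA 2. Removing a library lowered the total to 45 without NC 2, 51 without NC 3, 67 without siRNA 1, 35 without siRNA 2 and 55 without siRNA 3, and to 162 without NC 1. The balance of higher and lower genes moved with scaling, from 144 against 91 to 63 against 98 (39.1% higher) after median centring and to 202 against 231 (46.7% higher) with trends in GC content and length removed.

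**Figure D2:**
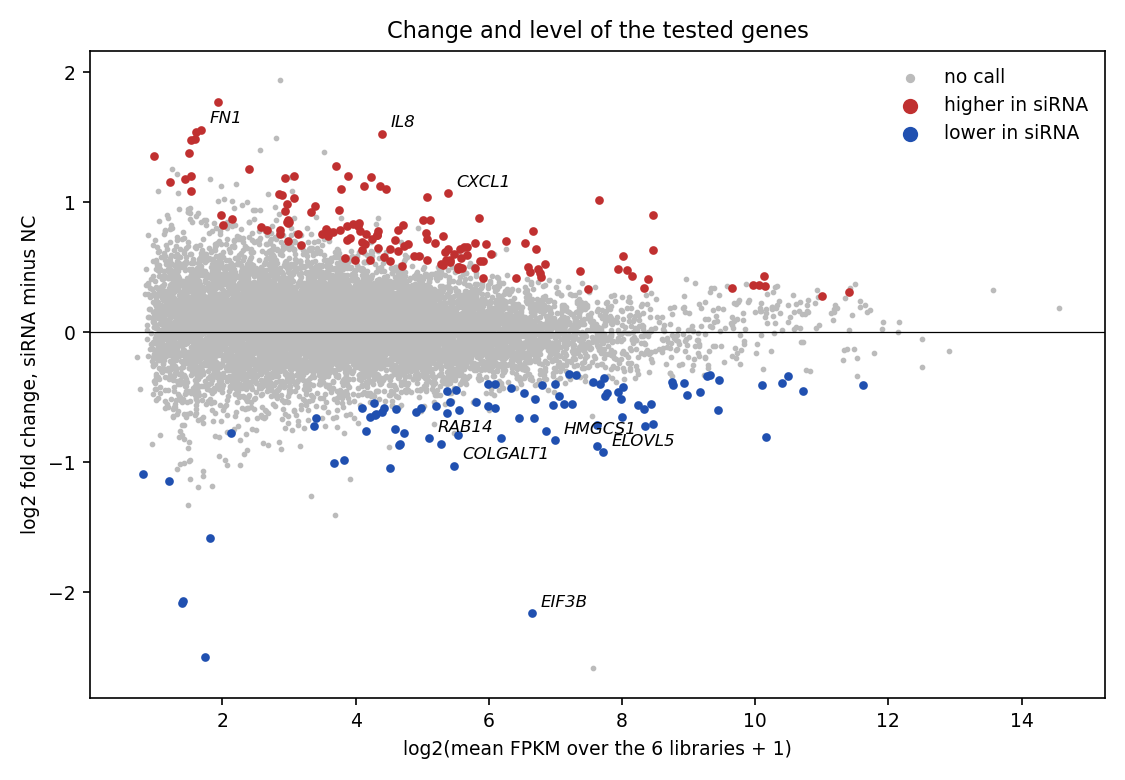
Log2 fold change (siRNA minus NC) of each of the 11569 tested genes against the log2 of its mean FPKM plus 1, with the 144 genes called higher in red, the 91 called lower in blue and genes without a call in grey. EIF3B lay at −2.16 and IL8 at 1.53.

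Inflammatory transcripts had the highest median change of the 35 lists tested as sets. Of the 20 tested NF-kB targets and cytokines, 9 rose, 0 fell and 11 had no call. When adjusted over the list alone, 17 rose. CXCL1 went from 26.1 to 55.9 FPKM (log2 change 1.07, adjusted p = 0.00234), CCL2 from 73.8 to 127 FPKM (0.78, adjusted p = 0.003) and the NF-kB inhibitor NFKBIA from 70.9 to 114 FPKM (0.68, adjusted p = 0.00923). The list was higher as a set (camera, adjusted p = 6.75e-15; adjusted p = 0.0158 with an estimated correlation), and its median log2 change was 0.57. The count of 9 dropped to 5 without NC 2, 5 without NC 3, 4 without siRNA 2 and 5 without siRNA 3. Among the 26 MAPK and AP-1 output genes, 3 rose (EREG, the phosphatase gene DUSP5 at 0.88 and JUN at 0.65), 0 fell and 23 had no call. Adjustment over the list alone gave 7 higher. That set was higher (camera, adjusted p = 0.000325; adjusted p = 0.2 with an estimated correlation). Of the 37 interferon-stimulated genes and RNA sensors, PSMB8 (0.66) and IRF1 (0.55) rose, 0 fell and 35 had no call. With adjustment within the list, 4 rose. That set was also higher (camera, adjusted p = 0.0431; adjusted p = 0.2 with an estimated correlation), and its 2 calls were lost with any library other than NC 1 left out.

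Lipid synthesis transcripts held the most falls of any of these lists. Of the 24 cholesterol biosynthesis genes, 0 rose, 10 fell and 14 had no call. When adjusted over the list alone, 18 fell. HMGCS1, which makes the substrate of the rate-limiting reductase, fell by 0.83 on the log2 scale (from 162 to 90.7 FPKM, adjusted p = 0.00256), the sterol isomerase EBP by 0.71, the feedback regulator INSIG1 by 0.59 and the squalene synthase FDFT1 by 0.56. The set was lower (camera, adjusted p = 6.23e-20; adjusted p = 0.0158 with an estimated correlation), with a median log2 change of −0.37. The count of 10 dropped to 5 without NC 2, 4 without NC 3, 5 without siRNA 1, 3 without siRNA 2 and 6 without siRNA 3. Of the 19 fatty acid synthesis genes, 0 rose, 4 fell (ELOVL5, FASN at −0.72, ACSS2 at −0.49 and the desaturase SCD at −0.40) and 15 had no call. Over the list alone, adjustment gave 9 lower. That set was lower (camera, adjusted p = 3.53e-09; adjusted p = 0.0926 with an estimated correlation), and its count was 2 without NC 2 and 1 without siRNA 2. Among 23 glycolysis genes only PKM had a call (−0.34), 22 had none, the count was also 1 when adjusted over the list alone, and the set had no call (camera, adjusted p = 0.0939). PKM kept its call only without NC 1. None of the 39 genes of mitochondrial oxidative phosphorylation had a call by limma-trend on FPKM (8 at an unadjusted p under 0.05; 3 lower by scaled counts). With adjustment within the list, 3 fell. That set was lower (camera, adjusted p = 0.000911; adjusted p = 0.0926 with an estimated correlation).

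In the translation machinery, EIF3B was the member of the 14 eIF3 subunits that changed, and the other 13 had no call, with the count again 1 when adjusted over the list alone. EIF3K, EIF3F and EIF3M, the most abundant subunits, had log2 changes of 0.14, 0.05 and 0.19 (adjusted p = 0.251, 0.78 and 0.397), and that of EIF3F turned negative after median centring or removal of GC and length trends. The median of the eIF3 list was 0.03, turning negative under the same settings, and its mean was −0.14. Camera gave the list no call (adjusted p = 0.417), whereas fry placed it lower (adjusted p = 0.0334). The list includes EIF3B itself (log2 change −2.16) and was not tested without it. Its mean and the fry result therefore do not describe the other subunits. Of 29 other translation initiation factors, EIF4G2 (0.64) and EIF6 (0.46) rose, EIF5A (−0.41) fell and 26 had no call. Adjustment over the list alone gave 4 higher and 1 lower. Their median was −0.02 and their mean 0.05, the mean turning negative after median centring and the median turning positive after quantile normalisation, and the set had no call (camera, adjusted p = 0.817). No initiation factor of this list had a call without NC 2, NC 3 or siRNA 3, and 1 did without siRNA 1 or siRNA 2. Of the 77 cytosolic ribosomal proteins, 6 rose, 0 fell and 71 had no call, RPL24 (0.36), RPS10 (0.36), RPL10A (0.35) and RPS3 (0.31) among the 6. When adjusted over the list alone, 39 rose. That set was higher (camera, adjusted p = 4.64e-15; adjusted p = 0.169 with an estimated correlation), and its count was 3 without siRNA 1 and 0 without NC 2, NC 3, siRNA 2 or siRNA 3. No gene had a call by limma-trend among 40 ribosome biogenesis genes (6 at an unadjusted p under 0.05, 3 higher and 1 lower by scaled counts; 1 higher when adjusted over the list alone; camera, adjusted p = 0.619). The same held for 20 aminoacyl-tRNA synthetases (3 at an unadjusted p under 0.05, 0 by scaled counts and 0 when adjusted over the list alone; camera, adjusted p = 0.901). The means of these lists were 0.07 and 0.03, that of the synthetases turning negative after median centring or removal of GC and length trends.

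Protein folding and stress transcripts split. Of 24 endoplasmic reticulum chaperone and unfolded protein response genes, 0 rose, 4 fell and 20 had no call. With adjustment within the list, 9 fell. The calcium-binding chaperone CALR went from 837 to 554 FPKM (log2 change −0.59, adjusted p = 0.0039), with HERPUD1 at −0.56, HSP90B1 at −0.55 and HSPA5 at −0.33. The set was lower (camera, adjusted p = 7.02e-07; adjusted p = 0.0504 with an estimated correlation), and its count was 1 without any of NC 2, NC 3 or a siRNA library. Of 32 ATF4 and integrated stress response targets, TRIB3 (0.64), VEGFA (0.53) and GDF15 (0.49) rose, ASNS (−0.32) fell and 28 had no call. Within-list adjustment gave 11 higher and 3 lower (camera higher, adjusted p = 0.0493; adjusted p = 0.459 with an estimated correlation). Its count was 2 without siRNA 1 and 0 without NC 2, NC 3, siRNA 2 or siRNA 3. The hypoxia response list of 23 shared VEGFA as its only call, also 1 when adjusted over the list alone (camera higher, adjusted p = 0.0356; adjusted p = 0.422 with an estimated correlation), and VEGFA kept its call only without NC 1. Of 21 heat shock genes, CRYAB (1.36, from 0.10 to 1.85 FPKM) rose, DNAJB1 (−0.49) and HSPA1B (−0.75) fell and 18 had no call, with 2 higher and 3 lower when adjusted over the list alone and no call for the set (camera, adjusted p = 0.1). CRYAB had no call on scaled counts (adjusted p = 0.121), and the list had 0 calls without NC 2 or siRNA 3 and 1 without NC 1, NC 3 or siRNA 2. Of 19 NRF2 targets, HMOX1 (0.71) and ABCC3 (0.64) rose, NQO1 (−0.42) and PGD (−0.35) fell and 15 had no call. Adjusted alone, the list gave 6 higher and 2 lower (camera, adjusted p = 0.551). The NRF2 count was 2 without NC 1 and 0 without any other library. By limma-trend no gene had a call among 33 proteasome genes (5 at an unadjusted p under 0.05, 2 lower by scaled counts; 1 lower when adjusted over the list alone; the set lower by camera, adjusted p = 0.0337; adjusted p = 0.222 with an estimated correlation). The same held for 33 lysosome and autophagy genes (6 at an unadjusted p under 0.05, 4 higher by scaled counts; 1 higher when adjusted over the list alone; camera, adjusted p = 0.278), whose median was −0.06 against a mean of 0.01 that turned negative after quantile normalisation, median centring or removal of GC and length trends. It also held for 5 metallothioneins (2 at an unadjusted p under 0.05, 0 by scaled counts; 1 higher when adjusted over the list alone; camera, adjusted p = 0.99).

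Few cell cycle genes had calls. None of the 26 genes for cyclins, CDKs and regulators of G1/S had a call by limma-trend on FPKM (9 at an unadjusted p under 0.05; 3 higher and 3 lower by scaled counts), with 2 higher and 1 lower when adjusted over the list alone, and the set had none (camera, adjusted p = 0.901; mean 0.04, turning negative after quantile normalisation, median centring or removal of GC and length trends). CDK4, CCND1 and MYC, the most abundant of these, had log2 changes of −0.11 (adjusted p = 0.594), 0.32 (adjusted p = 0.0773) and −0.41 (adjusted p = 0.0906), and the scaled counts called CCND1 higher (adjusted p = 0.00578) and MYC lower (adjusted p = 0.00901). Of 45 DNA replication genes, RPA1 and the ribonucleotide reductase subunit RRM2 (−0.76, from 145 to 85.5 FPKM, adjusted p = 0.00297) fell, 0 rose and 43 had no call. Adjusting within the list gave 4 lower (camera lower, adjusted p = 0.000131; adjusted p = 0.114 with an estimated correlation). The abundant members TYMS (−0.14), RPA3 (−0.44) and POLD2 (0.19) had no call. Of 53 genes of G2/M and mitosis, KIF20A (−0.58) and CKS2 (−0.46) fell, UBE2C (0.42) rose and 50 had no call. Within-list adjustment gave 2 lower and 1 higher (camera lower, adjusted p = 0.00429; adjusted p = 0.5 with an estimated correlation). Of 9 replication-dependent histones, HIST1H2BK (−0.40) fell and 8 had no call, and 5 fell when adjusted over the list alone (camera lower, adjusted p = 0.000162; adjusted p = 0.2 with an estimated correlation). The median of this list, −0.40, was the lowest of the 35. GADD45A (0.54) was the only call among 25 p53 targets (3 higher and 1 lower when adjusted over the list alone; camera, adjusted p = 0.318). Of 26 apoptosis regulators, the inhibitors BIRC3 (0.60) and BCL2L1 (0.45) and the activator PMAIP1 (0.56) rose, 0 fell and 23 had no call. Adjusted alone, the list gave 4 higher (camera higher, adjusted p = 0.0159; adjusted p = 0.162 with an estimated correlation). Leaving out NC 1 gave 1 apoptosis call and leaving out any other library 0. For G2/M and mitosis, leaving out any library other than NC 1 gave 0, while the calls of HIST1H2BK and GADD45A were lost with any one library left out, and the DNA replication count was 1 without NC 2, NC 3 or siRNA 2.

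RAB14 was the only call among 44 RAB GTPases on FPKM, also when adjusted over the list alone, and 43 had none. On scaled counts RAB14 fell as well, and 2 other members rose. The abundant RAB11A, RAB7A and RAB6A had log2 changes of −0.11, −0.04 and −0.08 (adjusted p = 0.571, 0.789 and 0.649), with RAB7A turning positive after quantile normalisation. The mean of the RAB list was 0.05, turning negative after median centring or removal of GC and length trends. Camera gave no call with a direction of lower (adjusted p = 0.901), whereas fry placed the list higher (adjusted p = 0.0467). On scaled counts fry gave the list no call (adjusted p = 0.818). Of 30 spliceosome core genes, PRPF3 (−0.61) and SNRNP70 (−0.47) fell, 0 rose and 28 had no call. Adjusting within the list gave 4 lower (camera lower, adjusted p = 1.39e-05; adjusted p = 0.108 with an estimated correlation), with 1 call without NC 1 and 0 without any other library. STMN1 (−0.39), which destabilises microtubules, was the only call among 18 genes of the microtubule cytoskeleton (1 higher and 3 lower when adjusted over the list alone; camera, adjusted p = 0.144), kept only without NC 1. The 13 genes of the RNA interference machinery had no call by limma-trend (1 at an unadjusted p under 0.05, 2 higher by scaled counts; 0 when adjusted over the list alone; camera, adjusted p = 0.551).

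The 5 calls of the YAP/TEAD, extracellular matrix and mesenchymal lists were rises. Of 21 YAP/TEAD targets, the receptor kinase AXL (0.64, from 80.8 to 126 FPKM) and NT5E (0.42) rose, 0 fell and 19 had no call. Within-list adjustment gave 5 higher (camera higher, adjusted p = 0.00429; adjusted p = 0.42 with an estimated correlation), with 0 calls without NC 2 or siRNA 2 and 1 without any other library. Of 21 extracellular matrix genes, COL7A1 (1.03, from 4.56 to 10.4 FPKM) and LAMB2 (0.52) rose, 0 fell and 19 had no call. Adjusted alone, the list gave 3 higher (camera higher, adjusted p = 0.0223; adjusted p = 0.305 with an estimated correlation), with 0 calls without siRNA 2 and 1 without NC 2, NC 3, siRNA 1 or siRNA 3. Of the epithelial genes, the tight junction gene CLDN1 (0.80) rose and the splicing regulator gene ESRP1 (−1.09, from 1.39 to 0.11 FPKM) fell. CLDN1 kept its call only without NC 1, and ESRP1 lost it with any one library left out and on scaled counts (adjusted p = 0.273). Of 21 mesenchymal and EMT genes, FN1 (1.56, from 0.65 to 3.74 FPKM) rose and 20 had no call. Within-list adjustment gave 4 higher (camera higher, adjusted p = 0.0207; adjusted p = 0.334 with an estimated correlation), and FN1 kept its call only without NC 1. The fibroblast transcripts COL1A2 (0.01 FPKM in NC, 0.76 FPKM in siRNA) and DCN (0.15 and 0.95 FPKM) also stood higher in every siRNA library than in any NC library, at levels too low to be tested, and the keratinocyte transcript KRT13 stood at 3.27 FPKM in NC and was listed at 0 in the siRNA libraries. None of the 7 tested pancreatic cell identity genes had a call by limma-trend (3 at an unadjusted p under 0.05, 2 higher by scaled counts; 1 higher when adjusted over the list alone; camera higher, adjusted p = 0.0493; adjusted p = 0.252 with an estimated correlation).

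**Figure D3:**
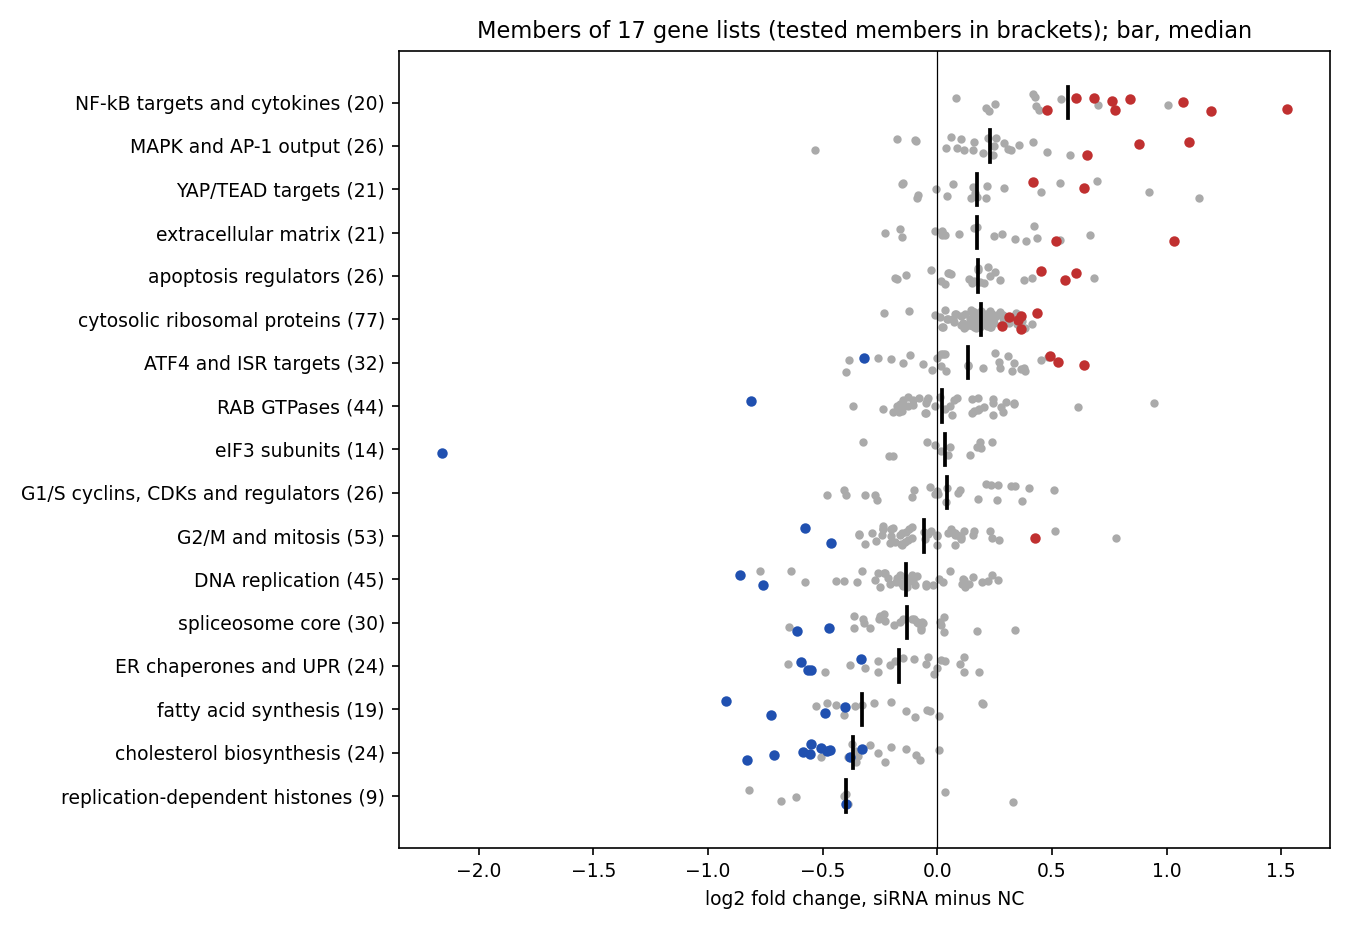
Log2 fold change (siRNA minus NC) of the tested members of 17 gene lists, with members called higher in red, called lower in blue and without a call in grey, and the median of each list as a bar. The medians of the NF-kB list (0.57) and the cholesterol list (−0.37) lay on opposite sides of 0, and the small medians of the eIF3 list (0.03), the RAB list (0.02) and the G1/S list (0.04) changed sign after median centring.

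Most markers of other cell types were low, CD68 and COL1A1 (10.5 FPKM in NC, 9.74 FPKM in siRNA) being exceptions. None of 19 markers of pancreatic acinar and endocrine cells reached the level for testing. Of 17 markers of haematopoietic and endothelial cells 3 were tested, and CD68, a lysosomal protein that carcinoma cells also express, rose from 158 to 198 FPKM (0.33, adjusted p = 0.0451; 1 higher when adjusted over the list alone), while CD14 (−0.34) and ITGAM (−0.14) had no call. The call of CD68 was kept only without NC 1. The 3 tested of 13 fibroblast and stellate cell markers (THY1 at 0.45, RGS5 at 0.73 and COL1A1 at −0.16) and the 4 tested of 15 markers of liver, kidney-derived and neural cell lines had no call by limma-trend (1 and 0 at an unadjusted p under 0.05, 0 by scaled counts), nor did any when adjusted over the list alone.

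Across the 35 lists with enough tested genes, camera on FPKM with a preset correlation called 11 higher and 9 lower. With an estimated correlation it called 1 higher (NF-kB) and 1 lower (cholesterol). On scaled counts the estimated correlation also called the endoplasmic reticulum and fatty acid synthesis lists lower (camera, adjusted p = 0.0316 for each). On FPKM fry, which asks whether the genes of a set move on balance 1 way, called 11 higher and 8 lower. The mixed test of fry, which asks whether genes of a set change in either direction, called 32. In 2808 of the tested genes (24.3%) the groups did not overlap, against 10% by chance. The same model on the deposited scaled counts called 1075 genes, 745 higher and 330 lower, including 211 of the 235, with the same sign in all 211. The p-values measure only the spread between these libraries, since the labels call them replicate biosamples without saying whether they came from separate cultures. Values of HSPA1B, EIF3C, EIF3CL, ribosomal protein genes with near-identical copies, histone genes whose transcripts mostly lack a poly(A) tail and genes that overlap others are uncertain.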

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

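The fits on scaled counts, on scaled counts of at least 10 and with GC and length trends removed were chosen after the data were seen. The other alternatives were fixed before the data were examined. The planned count models (edgeR with other normalisations, DESeq2, voom, filters on counts) and the use of transcripts in place of genes were not run, because the table holds no raw counts and lists genes. EIF3B kept its direction and its call in all 16 alternatives, with log2 changes from −2.23 to −2.10. Of the 79 named genes with a call, 15 kept it in every alternative and 0 changed sign. The cause was not tested for any change below unless the setting itself removes genes or libraries.

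The 235 calls became 31 without the low-value filter (16 higher, 15 lower; 15951 genes tested), 38 at 2-fold or more (28 and 10) and 433 with GC and length trends removed (202 and 231). They became 1075 with scaled counts (745 and 330) and 1064 with scaled counts of at least 10 (745 and 319). Quantile normalisation gave 88 higher and 80 lower, and median centring 63 higher and 98 lower. Leaving out a library, which removes replicates, gave 35 to 162 calls, 16 to 96 higher and 19 to 66 lower. RAB14 missed the threshold without the filter (log2 change −0.81, adjusted p = 0.0583; from 5.15e-06 over the alternatives) and its change ranged from −0.89 to −0.72 with a library left out. The replicate number as a block gave 138 calls (87 higher, 51 lower). After the group mean of each gene was subtracted, same-numbered libraries had correlations of −0.09, −0.07 and 0.02. These values gave no sign that the numbers pair the libraries, although siRNA 3 was closest to NC 3 among the NC libraries.

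Lists called by camera on FPKM were 20, or 2 with an estimated correlation, and 13 to 20 with a library left out. The adjusted p-values with an estimated correlation were 0.169 (ribosomal proteins), 0.459 (ATF4), 0.0504 (endoplasmic reticulum), 0.114 (DNA replication), 0.50 (G2/M), 0.162 (apoptosis), 0.20 (interferon), 0.20 (MAPK), 0.42 (YAP), 0.334 (mesenchymal), 0.305 (matrix), 0.0926 (fatty acid), 0.422 (hypoxia), 0.0926 (oxidative phosphorylation), 0.20 (histones), 0.222 (proteasome), 0.108 (spliceosome) and 0.252 (pancreatic identity). With fry they were 0.0334 for eIF3 subunits (EIF3B included), 0.392 for G2/M and 0.0538 for YAP. They were 0.0843 for the proteasome and 0.0467 for RAB GTPases with fry. The direction of the RAB list reversed to higher, and on scaled counts fry gave that list an adjusted p of 0.818. GC and length removal gave 0.0902 for matrix and 0.037 for glycolysis. Median centring gave 0.084 for ATF4 and 0.0936 for hypoxia, and no filter gave 0.084 for ATF4 and 0.882 for pancreatic identity. Quantile normalisation gave 0.0503 for interferon, 0.0771 for oxidative phosphorylation, 0.331 for the proteasome and 0.0604 for pancreatic identity. The replicate block gave 0.0667 for ATF4, 0.0515 for interferon and 0.0715 for pancreatic identity. Scaled counts gave 0.0691 for interferon, 0.0691 for hypoxia and 0.0400 for heat shock, and scaled counts of at least 10 gave 0.0968, 0.0755 and 0.0193 for these and 0.304 for pancreatic identity. The filter at 5 FPKM gave 0.104 for interferon, 0.132 for mesenchymal genes, 0.0518 for matrix, 0.0564 for hypoxia and 0.0518 for the proteasome. With a library left out the adjusted p ran from 0.0116 to 0.228 (ATF4), 2.58e-06 to 0.0974 (G2/M), 0.00659 to 0.0862 (apoptosis), 0.00659 to 0.0857 (matrix), 0.0258 to 0.381 (glycolysis), 0.0135 to 0.276 (heat shock), 0.0118 to 0.164 (hypoxia), 0.0118 to 0.115 (interferon), 0.0109 to 0.0638 (mesenchymal), 0.0274 to 0.153 (pancreatic identity) and 0.0116 to 0.0929 (proteasome).

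The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 235 calls and the highest of the others 0, so 1 of the 10 splits reached 235. With 10 splits the share cannot go under 0.05. The 568 genes with 1 annotated transcript, fitted and adjusted on their own, gave 42 calls on FPKM and 79 on scaled counts. Over all genes the calls were 235 and 1075. The gap was smaller among the 568, but the 2 comparisons were adjusted over different numbers of genes. The 42 and 79 are therefore not parts of the 235 and 1075. In simulated data the model recovered 54% of log2 changes of 1 and 18% of those of 0.5.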

Other observations

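The tests of chance among words, of base composition, of longer matches of the word, of RAB14 among the genes that carry it, of genes listed at 0, of marker levels for cells of another type and of the word outside the 3' UTR were chosen after the result was seen. So was the first keratinocyte list. Among 238 KEGG pathways written in the deposited table, camera with a preset correlation called 24 higher and 10 lower in siRNA. With an estimated correlation it called 0, and the lowest adjusted p was 0.405. TNF signaling was higher, with 9 of 67 tested genes risen, 0 fallen and a median log2 change of 0.25 (adjusted p = 5.56e-07). ECM-receptor interaction (5 of 39 risen, median 0.25, adjusted p = 0.000518), focal adhesion (9 of 105 risen, median 0.14, adjusted p = 0.00158) and Notch signaling (0 of 40 risen, median 0.24, adjusted p = 0.0016) were also higher with the preset correlation. Steroid biosynthesis (4 of 15 fallen, median −0.26, adjusted p = 1.71e-08), the spliceosome (9 of 125 fallen, median −0.14, adjusted p = 1.18e-07) and terpenoid backbone biosynthesis (5 of 20 fallen, median −0.07, adjusted p = 0.0016) were lower with it.

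Genes whose 3' UTR holds the word GAATCGA stood lower in the siRNA libraries than other genes. The word had the lowest z of 15473 words of 7 bases (−8.66, and −8.88 on scaled counts), with −4.45 for the next, AATCGAA, which overlaps it. The 138 genes with the word had a median log2 change of −0.13, and 12 fell and 0 rose, while the 10832 without it had a median of 0.05, and 75 fell and 130 rose. On scaled counts 24 fell and 5 rose with the word, against 289 and 707 without it. CPD, COLGALT1, CDCA7, ELOVL5, VDAC1 and RPA1, which are 6 of the 10 largest falls among genes with a mean of at least 5 FPKM, held the word in the 3' UTR, and 0 of the 10 largest rises at that level did. Since the word was chosen for its low z in these same changes, the counts of falls and rises are not separate evidence. RAB14 held it in the 3' UTR, on GRCh38 chromosome 9 at 121180722 to 121180728 in exon 8 of 8. EIF3B held it in the coding sequence, on chromosome 7 at 2360755 to 2360761 in exon 2 of 19, and 4.80% of the tested transcripts held it anywhere.

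A candidate explanation is that the seed of the siRNA, whose sequence the labels do not give, pairs with this word, and RAB14 may then have fallen through its own site rather than through the loss of EIF3B. Chance among words, base composition and a single deviant library were argued against: the largest z of any word was 5.13 in size over 100 permutations, the lowest z of 105 words of the same bases was −2.80, and z stayed at or below −7.68 with each library left out. The 47 genes with GAATCGAA differed in median log2 change by −0.0861 from the 91 with GAATCGA alone (permutation test, one-sided p = 0.157). This difference did not settle seed pairing. Pairing with shorter matches predicted a z under −2 for the 441 genes with AATCGA but not GAATCGA. Their z was −1.54, so that prediction was not met. Their median log2 change was 0.04, and 7.92% of 4092 words of 6 bases had a z as low or lower. The miss lay within the spread of z, so a weak effect of shorter matches was not excluded. Of the 138 genes with the word, 5.80% (8, RAB14 included) fell at least as far as RAB14, against 0.305% of genes without it. The word was picked by its low z in these same changes, so this excess is not separate evidence. Loss of EIF3B and pairing with RAB14 cannot be told apart for RAB14, because the design holds no group with another siRNA against EIF3B. The labels also do not say whether a single siRNA or a pool was used.

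For the lower cholesterol synthesis genes and higher NF-kB targets, with GC and length trends removed, all 10 called cholesterol genes and 88.9% of the 9 called NF-kB genes (8, the other lacking a GC value) kept their calls, and the depth of the groups overlapped, with 11.1 M (1000000) reads in the shallowest siRNA library against 13.5 M in the deepest NC library, which argues against these as the whole cause. Fibroblasts or stellate cells were argued against for the cholesterol genes, whose median fall needs a share of at least 22.5%, since the 13 markers of these cells had a median of 0.76 FPKM in siRNA, while cells of other types were not decided on. For the NF-kB genes cells of another type cannot be told apart from a rise in PANC1, since the largest gain in the first fibroblast list was 1.46 FPKM, COL5A2 (107 to 120 FPKM) and SPARC (4.62 to 8.17 FPKM) of the further genes stood higher in all siRNA libraries without a call, the median gain of the 9 called genes was 20.4 FPKM, and the level of these genes in such cells is not known here. Pairing within the 3' UTR was argued against for the cholesterol genes, since 0 of the 10 held GAATCGA there in the transcript used. The 3' UTRs of their other transcripts were not examined. HMGCS1 (1 of the 10) held the word elsewhere in its transcript, so pairing outside the 3' UTR cannot be told apart for that gene. Loss of EIF3B and effects of the siRNA through other transcripts both remain open, and a difference in handling between the groups, for which the labels give no batch, cannot be told apart from them.

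S100A9 (a mean of 4.69 FPKM in NC), S100A8 (3.30 FPKM) and KRT13 (3.27 FPKM) were called lower. They were among 13 of the 14 keratinocyte genes noticed in these libraries that were listed at 0 in every siRNA library, and the pancreatic identity list also holds 3 of the 14. A candidate source is RNA of squamous epithelium in the NC libraries. Of 42 further keratinocyte genes, listed before their values were seen, 33 had a mean above 0 and under 5 FPKM. Of these 33, 21.2% (7) stood higher in all NC than in all siRNA libraries, against 3.94% of all genes at that level. By chance 5% would do so, and 3 of the 42 reached a mean of 1 FPKM in siRNA. The 7 had NC means of only 0.05 to 0.23 FPKM, and the share over all genes was not matched to so low a level. LYPD3 (2.84 FPKM in NC, 2.91 FPKM in siRNA), PRSS27 (1.88 and 2.39 FPKM) and CLIC3 (1.59 and 0.81 FPKM), the tested members of the 33, had no call. The NC mean was higher for 27 of the 33. RNA of fibroblasts or fat cells in the siRNA libraries stayed open. Of 21 further genes of these cells with a mean above 0 and under 5 FPKM, 14.3% stood higher in all siRNA libraries. So did 27.3% of 11 from the first fibroblast list, against 9.45% of all genes at that level. The mean was higher in siRNA for 18 of the 21, 10 of the 11 and 4272 of all 7261. Of the 29 further genes of these cells, 9 reached a mean of 1 FPKM in siRNA. All 8 genes that went from at least 0.3 FPKM in every NC library to 0 in every siRNA library were keratinocyte genes. 3 genes, FABP4 among them, went the opposite way. All 8 belong to the list noticed in these libraries, which was made after the values were seen, so this count is not separate evidence. A fall within the PANC1 cells cannot be told apart from an outside source, since these genes changed with the group and the labels name no batch.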
